A study of Drosophila melanogaster with 2 samples.

How the data were processed

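The samples were chromatin immunoprecipitation sequencing (ChIP-seq) libraries from whole Drosophila melanogaster embryos aged 0 to 18 hours. Per the labels, the flies carried a transgene for amos fused to eGFP, the fusion protein was pulled down with an anti-GFP antibody, and chromatin was sonicated to fragments of 200 to 800 bp. The 2 samples are labelled as biological replicates 1 and 2 of 1 group. No second group or control library was analysed here, so the comparisons set replicates, genomic positions, sequence windows and gene lists against each other.

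The text files deposited with the samples name the genome build (dm6, Release 6) and the kinds of peak list. Peaks were called on each replicate and on pooled reads and passed through the irreproducible discovery rate (IDR) procedure, per the labels of those lists. The aligner, the peak caller and their versions are not given in the sources used here. The deposited signal of a peak is the value that the authors' peak caller gave it, never negative and with a scale set in each set of reads. It was used only to describe, rank or filter peaks within a list. The deposited lists give the q value of a peak as −log10, and the deposited ranked lists give its global IDR as −log10. The lists hold no read counts, so the depth of each library is unknown and no interval or floor that needs depth is given. Intervals on shares of peaks are Wilson 95% intervals over peaks. Peaks and genes are not independent replicates, so such intervals and p-values describe these lists and not the spread between embryos.

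The 8 lists are an optimal and a conservative thresholded list from pooled reads, 1 thresholded list per replicate, and the 4 ranked lists behind them. The optimal list was the main list. Of the per-input values in the ranked lists, 2 columns (the signal of each region in both inputs) were used and 30 were not. Positions were analysed on the 6 main arms (2L, 2R, 3L, 3R, 4 and X, 133.9 Mb), and peaks elsewhere were left out. The annotation was Ensembl release 115 on assembly Release 6, with 13945 protein-coding genes on these arms. Coordinates are 1-based on dm6.

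Tests, gene lists, motifs and the rule for named genes were fixed before the data were examined. Replicate overlap was the share of replicate 2 peaks overlapping a replicate 1 peak by 1 bp or more, against 1000 random relocations on the same arm (one-sided permutation test, smallest possible p 0.001). Spearman's rank correlation of signal was taken over shared peaks. Promoter share was the share of summits within 500 bp of the transcription start site (TSS) of a protein-coding gene, against 1000 relocations (two-sided permutation test, smallest possible p 0.002). For each of 21 motifs, the share of windows reaching 50 bp to each side of the summit with a match on either strand was compared with the mean of windows 1000 bp to each side. Its test was a two-sided exact binomial (McNemar) test on discordant peaks against 1 flank drawn at random, with Benjamini-Hochberg (BH) adjustment over the 21 motifs.

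For 19 gene lists, a gene counted as having a peak if a summit lay in its body or within 5 kb. The share was compared with 10000 random lists of protein-coding genes matched on gene length in 20 bins (two-sided permutation test, smallest possible p 0.0002, BH over 19 lists). Random lists were not matched on closeness of genes, so p-values may be too small for lists of neighbouring genes that share peaks. The lists were proneural bHLH genes, neural precursor genes, Notch signalling, the E(spl) and Brd complexes, EGFR signalling, sensory neuron transcription factors, retinal determination, pan-neuronal genes, sensory cilium, glia, muscle and mesoderm, gut with hemocyte and fat body, epidermis, segmentation, Hox, cell cycle, olfactory with ionotropic receptors, odorant-binding proteins, and ribosomal proteins. Of the symbols, 4 were matched through older names and 7 were not found. Arm counts were tested with two-sided exact binomial tests against the arm's share of sequence (BH over 6 arms). Peaks in 1 replicate's list alone were compared with shared peaks by two-sided Fisher's exact tests (BH over 44 tests).

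Named genes are the first 25 distinct protein-coding genes met going down the optimal list by signal, by nearest TSS, then amos, and in each list up to 4 members with the highest peak signal. The signal given for a list member is that of its strongest peak in the gene body or within 5 kb, and neighbouring genes can share a peak. Any other gene named was chosen after its values were seen.

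Alternatives were the conservative list, the peaks above the median signal of a list, each replicate's list alone, wider or narrower windows, further flanks, other overlap rules, other gene domains, no length matching, peaks matched on signal decile, and a shorter distance to amos. Peaks with a q value of 0.05 or less, and the median p over 200 draws of the flank of each peak, were added as alternatives after the data were seen. The code was tested on simulated data. A motif planted in 29.1% of 2000 windows was found in 32.6%, and 1 of 40 sets without a planted motif had a p under 0.05. Of 200 unplanted lists of long genes, 14 had a p under 0.05 with length matching and 200 without it. A planted overlap of 59.5% was measured as 59.9%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.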

Results

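Amos is a proneural basic helix-loop-helix (bHLH) protein of the Atonal family, which acts in the formation of olfactory sensory neurons and binds DNA at E-boxes (CANNTG) with its partner Daughterless. The data are positions bound in whole embryos aged 0 to 18 hours, from a pull-down of an amos-eGFP fusion with an anti-GFP antibody, although the antibody label reads amos. The group holds 2 biological replicates. The optimal list from pooled reads held 5860 peaks (5823 on the main arms) and the conservative list held 3116 (3115). The replicate 1 list held 6214 peaks (6213 on the main arms) and the replicate 2 list 2973 (2880). Signal in the optimal list ran from 2.06 to 4454.5 with a median of 120.1. In that list, 1375 peaks (23.6%) had a q value above 0.05, and their summits held CGATAG in 5.09% of cases, against 32.0% of the other 4448.

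The first question was how far the replicates share peaks. The strongest peak of both replicates was the same, beside CG15160, and the peak beside MESK2 was second in both. Of the 2880 replicate 2 peaks, 2281 (79.2%, 95% interval 77.7 to 80.6) overlapped a replicate 1 peak, against a mean of 2.54% and a maximum of 3.47% after relocation (one-sided permutation p = 0.001, the smallest possible). From the other side, 37.7% (36.5 to 38.9) of replicate 1 peaks overlapped a replicate 2 peak. Of the 100 strongest replicate 2 peaks, 60 were among the 100 strongest of replicate 1. Across the 2281 shared peaks, Spearman's rank correlation of signal was 0.629. Over all 102430 regions of the ranked list from both inputs, most of them below the threshold, it was 0.212.

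Most peaks lay at promoters. Of the 5823 summits in the optimal list, 4352 (74.7%, 73.6 to 75.8) were within 500 bp of a protein-coding TSS, 6.49 times the 11.5% found after relocation (two-sided permutation p = 0.002, the smallest possible). The share was 78.9% in replicate 1 and 72.8% in replicate 2, a mean of 75.9% ± 4.36 (SD, n = 2). The median distance from summit to TSS was 63 bp. By annotation, 48% of summits were intergenic and 23.1% in 5' UTRs, against 28.4% and 3.05% after relocation. Introns held 16.5%, coding exons 4.74%, non-coding exons 5.72% and 3' UTRs 1.97%, against 39.0%, 17.1%, 7.55% and 4.91%.

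The next question was which sequences lie at the summits of a bHLH protein's peaks. In windows reaching 50 bp to each side of the summit, CGATAG, the site of the insulator protein BEAF-32, was in 25.7% (24.6 to 26.8) against 2.58% of flanks, a ratio of 9.93 (exact binomial test, BH adjusted p = 7.19e-294). TATCGATA, the element bound by the transcription factor DREF, was in 13.7% against 0.335% (ratio 40.9, exact adjusted p = 3.45e-201). GGTCACACT, the core promoter motif bound by M1BP, was in 3.59% against 0.146% (ratio 24.6, exact adjusted p = 1.94e-54). E-boxes of any kind were in 40.4% of summit windows and 40.5% of flanks (ratio 0.999, exact adjusted p = 0.878). The Atonal-type E-box was in 0.618% against 0.567% (exact adjusted p = 0.472) and the Scute-type E-box in 2.06% against 2.5% (adjusted p = 0.243).

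Among single E-box hexamers, CAGCTG was in 8.64% of summit windows against 5.18% of flanks (ratio 1.67, exact adjusted p = 2.39e-11) and CACGTG in 1.75% against 1.17% (ratio 1.5, adjusted p = 0.0335). CAAATG (ratio 0.807, exact adjusted p = 0.000912) and the GATA motif WGATAR (ratio 0.835, adjusted p = 0.00191) were lower at summits. The rest of the 21 motifs did not pass the threshold in either direction, among them CAGGTG, CATATG, CATCTG, CATGTG, CAATTG, CAACTG, CAAGTG, GAGAGAG, the Zelda site, the Su(H) site and a CA repeat. Some calls depended on the flank drawn at random for the test: over 200 draws, CACGTG passed in 64.5%, CAAATG in 96.5%, CAGGTG and CATATG in 57.5% each, CAACTG in 48.5%, CATGTG in 33.0% and CATCTG in 27.0%, and the Scute-type E-box in 7%. In the replicates, CGATAG was in 24.5% and 36.1% of summit windows, a mean of 30.3% ± 8.18 (SD, n = 2), against a flank mean of 2.61% ± 0.282. TATCGATA was in 13.1% and 19.5% (16.3% ± 4.53). The CAGCTG call rested on replicate 1, with a ratio of 1.69 there (exact test, adjusted p = 1.74e-16) and 1.22 in replicate 2 (adjusted p = 0.384). CACGTG, CAAATG and WGATAR were not called in replicate 2 either, with ratios of 1.34, 0.849 and 0.960 on the same side of 1 and exact adjusted p of 0.590, 0.340 and 0.590. Over 9 alternatives, that replicate included, the CACGTG call was lost in 6, the WGATAR call in 5 and the CAAATG call in 2. GAGAGAG, the site of GAGA factor, had a ratio of 1.5 in replicate 1 (exact test, adjusted p = 0.00219) and 0.658 in replicate 2 (adjusted p = 0.483). It was called higher with flanks 2000 bp away (ratio 1.98, exact adjusted p = 5.81e-05) and with windows of 100 bp to each side (1.5, adjusted p = 0.000142), and lower in peaks above the median signal (0.452, adjusted p = 0.00488).

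**Figure D1:**
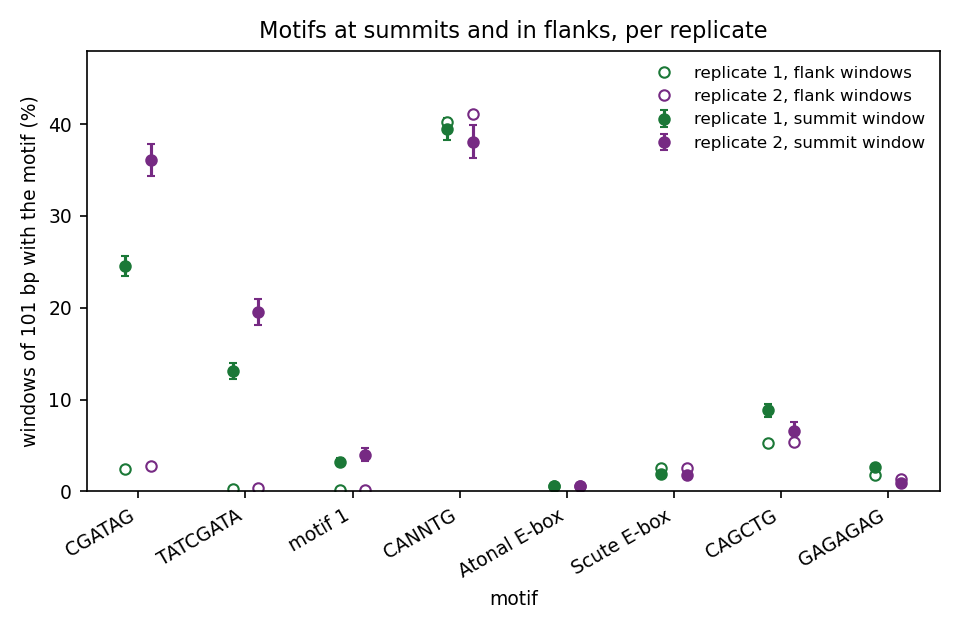
Share of windows (50 bp to each side of a centre, %) with each motif, per replicate: filled points are summit windows with Wilson 95% intervals and open points the mean of flank windows. CGATAG and TATCGATA stand above their flanks in both replicates, while any E-box is at 39.5% in replicate 1 and 38.1% in replicate 2 against flanks of 40.3% and 41.2%.

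CGATAG went with signal. In the lowest decile of the optimal list by signal it was in 4.63% (3.20 to 6.65) of summit windows, and in the highest decile in 70.4% (66.6 to 74.0). TATCGATA went from 1.37% to 34.4% and GGTCACACT from 1.37% to 4.81%. The rises were steeper in replicate 1, with CGATAG from 4.02% to 70.4% and TATCGATA from 0.322% to 36.2%, than in replicate 2, with CGATAG from 9.03% to 59.7% and TATCGATA from 5.90% to 25.3% with a maximum of 30.6% in the sixth decile. Promoter share was 53.2% in the lowest decile and 96.7% in the highest. E-boxes of any kind were in 42.2% (38.3 to 46.2) of the lowest decile and 31.8% (28.1 to 35.7) of the highest.

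**Figure D2:**
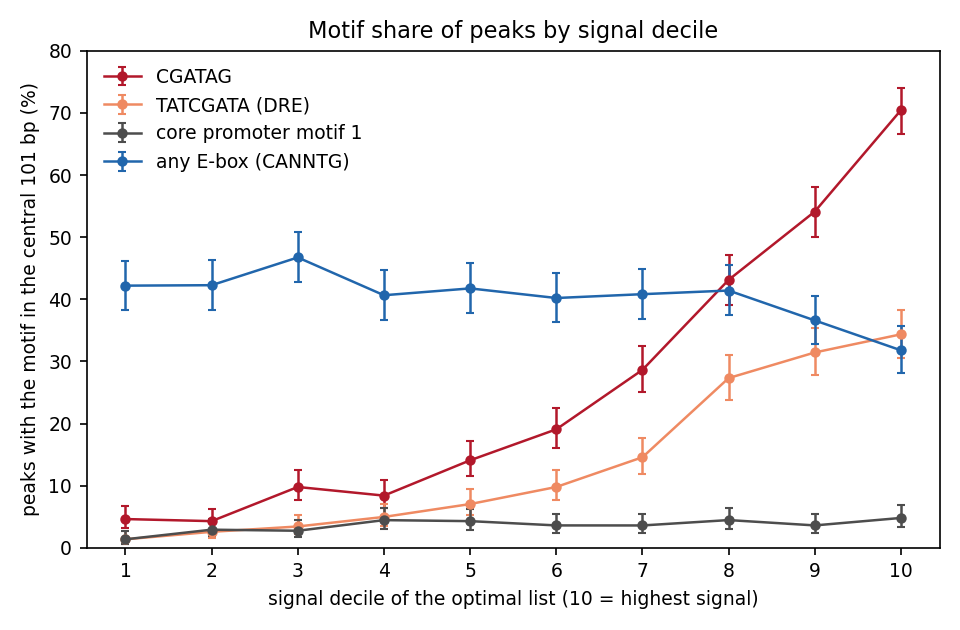
Share of peaks (%) with each motif within 50 bp of the summit, by decile of the optimal list from lowest to highest signal, with Wilson 95% intervals. CGATAG rises from 4.63% to 70.4%, and any E-box goes from 42.2% to 31.8%.

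The 25 genes beside the strongest peaks included genes of the ribosome, the proteasome and cohesin. CG15160 (signal 4454.5) came first, then MESK2 (4124) and RpL32 (3441), which encodes a ribosomal protein. CG2924, Creld, Rpn6 (a proteasome subunit), Pym, Daxx, Capr, Sumo (the small ubiquitin-like modifier), jagn, Snx27 (a sorting nexin), bun, SMC1 (a cohesin subunit), CG8613, CG11964, RpS2 (a ribosomal protein), Pcif1, Hsp110 (a chaperone), CG4502, EndoGI, CG11030, CG11779, Scsalpha1 (a subunit of succinyl-CoA synthetase) and RhoGAP93B (2219) followed. All 25 peaks were in both replicate lists, with their summits at most 159 bp from the TSS. CGATAG was in 21 of the 25 summit windows, TATCGATA in 5 and an E-box in 3. The RpL32 peak (3R 30046034 to 30046447, summit intergenic, 59 bp from the TSS) has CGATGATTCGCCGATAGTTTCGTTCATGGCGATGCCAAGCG at its summit. The Sumo peak (2L 6967476 to 6967864, summit intergenic, 9 bp from the TSS) has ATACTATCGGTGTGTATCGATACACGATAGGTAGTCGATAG there.

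Gene lists then asked whether peaks gather at genes of the proneural pathway or of other tissues. A peak in the body or within 5 kb was found for 9022 of 13945 protein-coding genes (64.7%). Ribosomal protein genes had peaks more often than matched random lists, and olfactory with ionotropic receptor genes less often. Of 85 ribosomal protein genes, 75 (88.2%) had a peak against 58.8% (permutation p = 0.0002, the smallest possible, BH adjusted p = 0.0019). RpS2 (2453) and RpS27 (1954) followed RpL32 in signal, and RpLP1 had 1581. Of 120 receptor genes, 33 (27.5%) had a peak against 65.4% (permutation p = 0.0002, adjusted p = 0.0019). Those with the highest signal were Ir51b (1524), Ir93a (1394), Ir60d and Ir60e (1084, a shared peak). Their summits were nearest to the TSSs of row, RpS30 and CG4612, genes outside the list named after their values were seen. Over the replicates, ribosomal protein genes had peaks in 82.9% ± 12.5 and receptor genes in 22.1% ± 7.66 of cases (SD, n = 2).

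No other list passed the threshold. Short lists left little room for a higher call: all 8 Hox and all 16 cell cycle genes had a peak, and neither list passed. For such lists a missing call does not argue against a higher share. Of 12 genes in the proneural bHLH list, 5 had a peak against 62.4% (permutation test, adjusted p = 0.457): dimm (966), da (202), which encodes Daughterless, emc (177), cato (142) and amos (62.8). The list is wider than its name, since da encodes the partner and emc an HLH protein without the basic region. The dimm peak was nearest to the TSS of Tsp39D. The amos peak lay in a coding exon of CG15160, 3232 bp from amos, and had a q value above 0.05. With q values of 0.05 or less, 4 of the 12 genes had a peak. The optimal list held no peak at ac, sc, l(1)sc, ase, ato, tap and Oli, which are named after their values were seen. Neural precursor genes had peaks in 14 of 22 cases against 73.5% (permutation adjusted p = 0.528), led by brat (455), neur (332), pros (286) and numb (275). Notch signalling had 11 of 15 against 75.6% (permutation adjusted p = 1), with mam (1160.2), a co-activator, Su(H) (795), the DNA-binding effector, and mib1 (765). The E(spl) and Brd complexes had 14 of 17 against 52.3% (permutation adjusted p = 0.0844), with E(spl)m7-HLH and E(spl)m8-HLH sharing a peak (359.6) near gro and BobA at 274. This list split by replicate, at 8 of 17 genes in replicate 1 (permutation test, adjusted p = 1) and 13 of 17 in replicate 2 (adjusted p = 0.0127). Neighbouring genes of these complexes that share a peak were counted separately, unlike scattered genes of the random lists. The replicate 2 p-value may therefore be too small. EGFR signalling had 16 of 18 against 76.9% (permutation adjusted p = 0.512), with Krn (1958, nearest to the TSS of Pep), S (1724) and Egfr (493).

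Sensory neuron transcription factors had peaks in 13 of 23 cases against 76.8% (permutation test, adjusted p = 0.140), with kn (993), exd (382) and fd3F (291). The kn peak was nearest to the TSS of BEAF-32. In replicate 2 alone this list had 5 of 23 against 53.1% (permutation adjusted p = 0.0161). Retinal determination had 7 of 10 against 76.9% (permutation adjusted p = 0.882), with ey (1352) and eya (369). Pan-neuronal genes had 13 of 24 against 76.6% (permutation adjusted p = 0.0855), with Nrg (1826), Nrx-1 (537) and Syt1 (389). Sensory cilium genes had 19 of 24 against 71.7% (permutation adjusted p = 0.684), with BBS8 (1581, the value also given for RpLP1), Arl6 (845) and unc (811). Odorant-binding proteins had 21 of 51 against 50.7% (permutation adjusted p = 0.457), with Obp73a (947) and Obp44a (736).

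Among the lists for other tissues, glia had peaks in 10 of 12 cases against 74.9% (permutation test, adjusted p = 0.864), with wrapper (1035) and loco (562). Muscle and mesoderm had 13 of 21 against 74.5% (permutation adjusted p = 0.493), with Dg (767), tin (629.9) and Mef2 (586). The gut, hemocyte and fat body list had 15 of 17 against 76.5% (permutation adjusted p = 0.528), with cyc (1824), which is a circadian clock gene, vkg (957), a collagen, and Hml (303). Epidermis had 10 of 16 against 76.4% (permutation adjusted p = 0.509), with pio (1167) and shg (642), which encodes E-cadherin. Segmentation genes had 9 of 20 against 71.6% (permutation adjusted p = 0.0844), with hh (503), hry (153) and odd (136). Hox genes had 8 of 8 against 76.8% (permutation adjusted p = 0.457), with Ubx (279), Dfd (249) and abd-A (238). Cell cycle genes had 16 of 16 against 72.0% (permutation adjusted p = 0.0760), with aurA (1545), a mitotic kinase, Cdk2 (987) and Rbf (873).

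**Figure D3:**
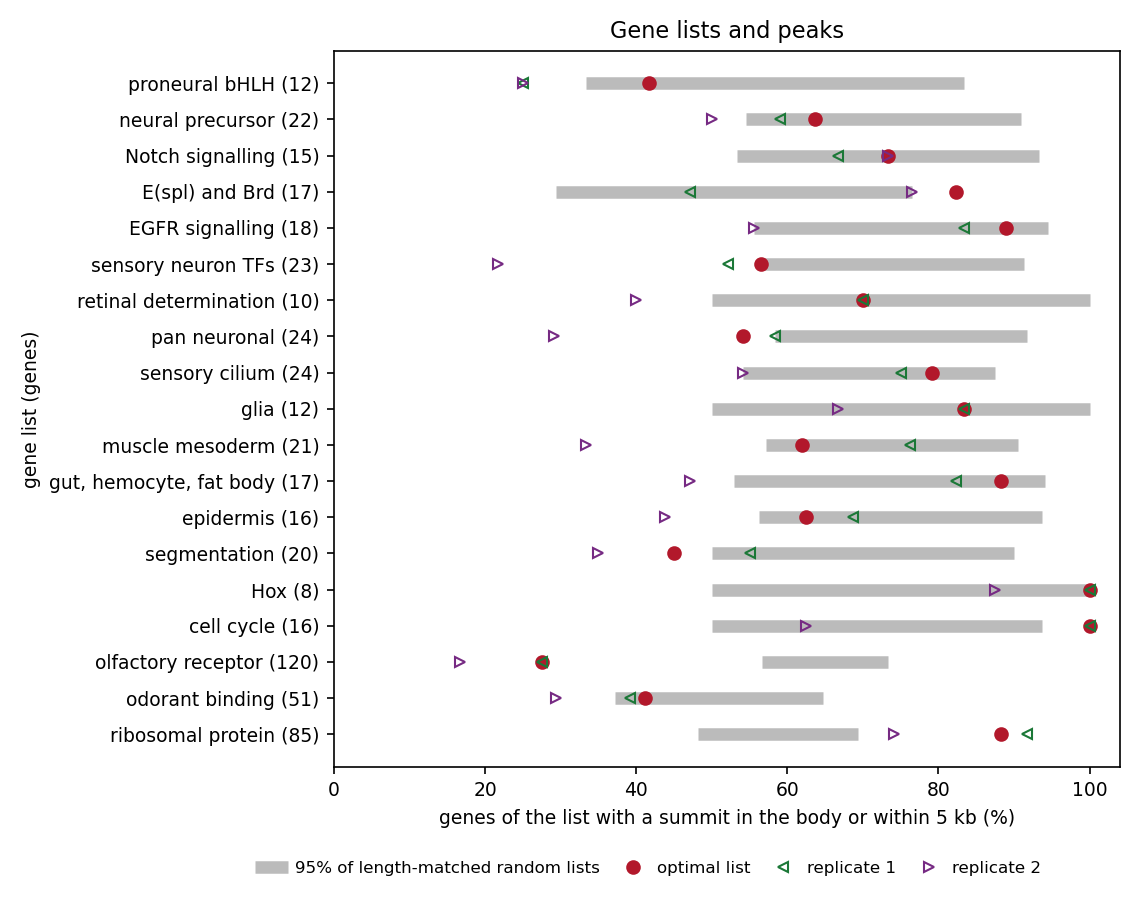
Share of the genes of each list (%) with a summit in the body or within 5 kb, for the optimal list and each replicate, with grey bars for 95% of length-matched random lists drawn for the optimal list. Ribosomal protein genes (88.2%) lie above their bar and olfactory with ionotropic receptor genes (27.5%) below it.

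At amos itself (FBgn0003270, 2L 18596136 to 18596921, minus strand), the optimal list held no summit within the gene and 6 peaks within 20 kb. The strongest peak of the whole list lay there, at 2L 18590654 to 18591056, with its summit intergenic, 36 bp from the TSS of CG15160 and 5281 bp from amos. Its signal of 4454.5 was 1.08 times the next and 37.4 times the median. The 50 bp to each side of its summit held 1 CGATAG and no E-box, and the whole peak of 403 bp held 1 E-box. The next 2 peaks by signal, 94.6 and 62.8, were beside CG10413 and in a coding exon of CG15160. Apart from the peaks of 4454.5 and 94.6, all of the 6 had a q value above 0.05, among them both peaks within 5 kb. Replicate 1 had 2 peaks within 20 kb and replicate 2 had 5. The replicate 2 list held a peak over the amos coding exon (2L 18596631 to 18596940, signal 53.4, rank 2264 of 2973), and the replicate 1 list held none there.

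**Figure D4:**
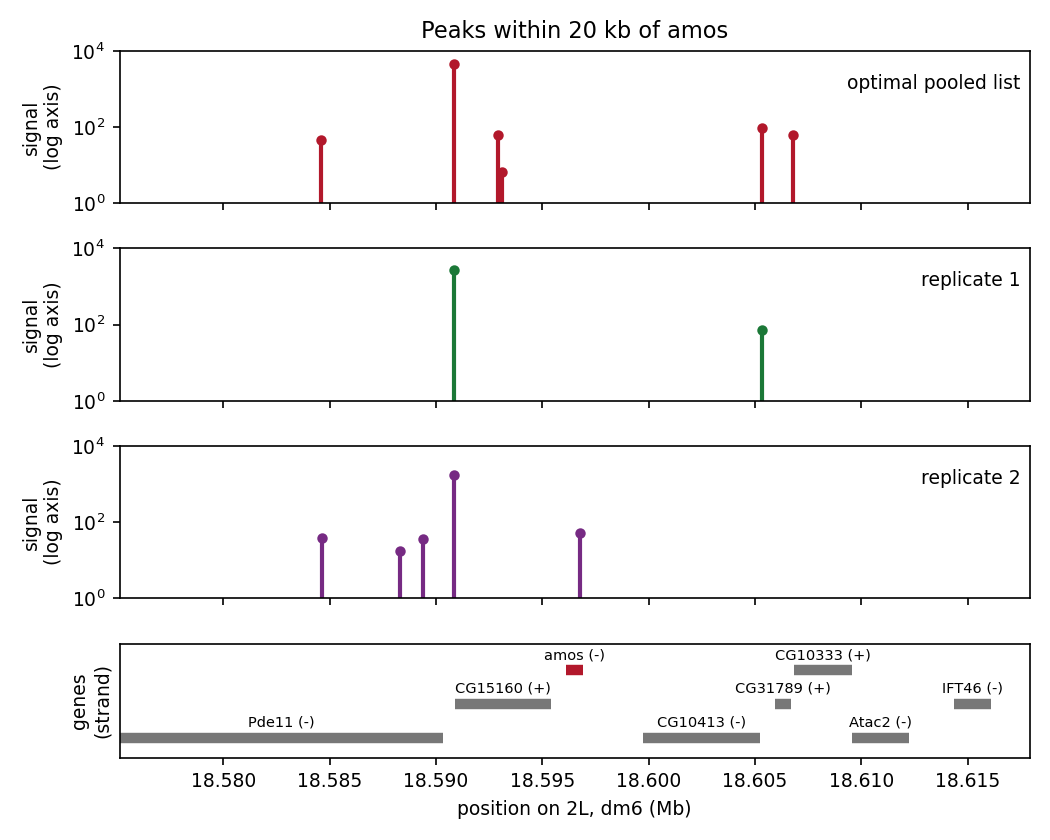
Peaks within 20 kb of amos on 2L (dm6, Mb), as summit position against signal on a log axis for each list, above the genes with their strands. The peak at the CG15160 promoter reaches 4454.5 in the optimal list, and a replicate 2 peak of 53.4 lies over amos.

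Peaks were spread unevenly over the arms. Arm 2R held 1306 peaks, 22.4% (21.4 to 23.5) of peaks on 18.9% of the sequence (fold 1.19, exact binomial test, BH adjusted p = 8.72e-11). Arm 4 held 23 peaks (fold 0.392, exact adjusted p = 5.28e-07) and 3L held 1136 (fold 0.929, adjusted p = 0.0102). Arms 2L (fold 1.01), 3R (0.968) and X (0.955) did not pass the threshold. In replicate 1 alone the 3L call was lost (fold 0.973, exact test, adjusted p = 0.331) and 3R was called (fold 0.942, adjusted p = 0.0194). Arm X turned to a fold of 1.12 in the conservative list (exact adjusted p = 0.00419) and 1.09 in peaks above the median signal (adjusted p = 0.0353).

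Peaks in 1 replicate's list alone differed from shared peaks. Of 3873 peaks in replicate 1 alone, 12.5% (11.5 to 13.5) had CGATAG at the summit, against 44.4% (42.4 to 46.5) of 2340 shared ones (Fisher's exact test, BH adjusted p = 2.70e-172). GAGAGAG was in 3.72% against 0.769% (exact adjusted p = 1.54e-13). Promoter share was 75.5% against 84.6% (exact adjusted p = 7.62e-17). Of 599 peaks in replicate 2 alone, 29.2% (25.7 to 33.0) were at promoters against 84.2% of 2281 shared ones (exact test, adjusted p = 7.96e-144). CGATAG was in 9.85% against 43% (exact adjusted p = 6.47e-58) and TATCGATA in 5.34% against 23.2% (adjusted p = 1.01e-26). Once replicate 1 peaks were matched on signal decile, promoter share turned, at 81.5% of those in replicate 1 alone against 75.1% of shared ones (exact adjusted p = 0.00126). With the same matching CGATAG was in 22.7% against 28.3% (exact adjusted p = 0.0121), and in replicate 2 the promoter shares were 29.6% against 86.7%. With 50% reciprocal overlap as the rule, peaks in replicate 2 alone were at promoters in 48.9% of cases and had CGATAG in 19.2%.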

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

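The test of strong promoters in general, the rise of CGATAG with signal in each replicate and the 3 tests on the strongest peak were chosen after the result was seen, and the tests of promoter location, base composition, CGATAG at the summit or the TSS and the threshold in replicate 2 were not. The design has 1 group, so no biological explanation was tested as such.

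Outside the main measurement, 37 peaks of the optimal list lay off the 6 main arms and entered no comparison. In the ranked list, 242 regions had a global IDR of 0.01 or less and were missing from the optimal list, with signals up to 2424.6. Of these, 197 were on the main arms, 48.2% of them at promoters and 13.7% with CGATAG at the summit against 3.81% in flanks. The densest group was 19 regions on X between 23300001 and 23400000. The thresholded lists were made with 1 input file more than the ranked lists, and what it holds is not given in the sources used here, so why these regions are missing stays open.

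The first pattern is CGATAG at summits, where E-boxes as a class (ratio 0.999) and those of the Atonal (1.09) and Scute (0.825) types were not called in either direction, although CAGCTG (1.67) and CACGTG (1.5) were called higher. Position near a TSS alone accounts for little of it. CGATAG was in 3.17% of windows placed alike at promoters without a peak and in 31.4% of promoter peaks. Those promoters were not matched on activity or type, and TATCGATA (0.896% against 17.0%) and GGTCACACT (1.82% against 4.64%) differed too. The comparison therefore cannot separate CGATAG from the type of promoter that has a peak. E-boxes went both ways in it. CAGCTG (5.88% against 9.79%) and CACGTG (0.804% against 1.36%) were more frequent in promoter peaks. CAAATG (9.28% against 6.66%), CAACTG (9.81% against 7.08%) and CAAGTG (7.63% against 6.14%) were less frequent there. Any E-box was in 40.4% against 39.3%. Base composition also accounts for little of the pattern, since the highest ratio among 59 other hexamers of the same bases was 3.56 against 9.93. Where summit and TSS were apart, CGATAG lay more often at the summit. Among 795 promoter peaks with the summit over 100 bp from the nearest TSS, it was in 16.0% of summit windows and in 8.81% of TSS windows (exact McNemar test, p = 2.45e-05). Most of the 4352 promoter peaks had their summit nearer to the TSS and were not part of that test. Strong promoters in general stay open. From the lowest to the highest signal decile of promoter peaks, GGTCACACT went from 2.29% to 5.06% and CGATAG from 3.90% to 70.8%. The estimated factors were 2.15 (bootstrap 95% interval 1.12 to 5.01) and 17.7 (11.7 to 30.1). But TATCGATA, a promoter motif that shares CGATA with CGATAG, went from 1.15% to 33.8%, a factor of 26.9 (14.1 to 97.2). In the peaks without CGATAG it went from 0.477% to 17.3%. Over all peaks, TATCGATA rose less in replicate 2 (5.90% to 25.3%) than in replicate 1 (0.322% to 36.2%). These estimated factors lie below the plain ratios of the shares, whereas the replicate factors given next are plain ratios over all peaks. The rise of CGATAG with signal in each replicate (17.5-fold in replicate 1 and 6.62-fold in replicate 2) restates that of the pooled list, so a CGATAG-binding protein such as BEAF-32, reached through a mislabelled sample, through an antibody that also binds another protein or through a fusion protein drawn to its sites, stays open, and no value here separates these.

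The second pattern is the strongest peak beside amos, the tagged gene. Extra copies of the region, as a transgene would bring, could raise its other peaks too. The median signal of the other ranked peaks within 20 kb was 18.2, at percentile 61.2 among genes, whose median was 17.3. A small raise, or a transgene shorter than this window, could be missed by that median, so extra copies stay open. Chance nearness stays open, since 0.0215% of protein-coding genes (3 genes) lay as near to this peak as amos, but that share would be small at any peak (at most 0.151%). A CGATAG site is present, with 1 match of CGATAG within 50 bp of the summit, as in most peaks of the highest decile. The peak may therefore be a CG15160 promoter peak of the same kind as the others, which leaves its place beside amos open.

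The third pattern is the number of peaks in replicate 1 alone. If the threshold in replicate 2 were the whole cause, these peaks would lie on ranked regions of replicate 2 more often than relocated ones, and 35.6% did against 39.9% after relocation. By definition these peaks touch no listed peak of replicate 2, which relocated ones may, and this lowers their share by an amount not measured. Peaks of replicate 1 alone on such regions had a median signal percentile of 88.0 there, against 52.9 after relocation, so the threshold may still account for some of them. A difference in depth between the libraries stays open, since the lists hold no read counts.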

How the results depend on the processing

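The alternatives with q values of 0.05 or less and with the median p over 200 draws of the flank were chosen after the data were seen. No paired analysis was possible because the samples form 1 group. Among the main results, 66 values kept their direction and side of the threshold or stayed within the spread, 20 moved, 1 passed the threshold and 1 reversed. Among single motifs, lists, arms and features, 252 kept theirs, 42 passed the threshold in an alternative alone, 19 lost it and 47 changed direction. Replicate overlap, promoter share, CGATAG and TATCGATA at summits kept their calls in all alternatives run. The calls of ribosomal protein and receptor genes held in all 8 of theirs. Lists that passed the threshold in alternatives alone and were higher than random lists were cell cycle (4 of 8) and E(spl) and Brd (1). Those that passed it and were lower were odorant-binding proteins (3), pan-neuronal, segmentation and sensory neuron transcription factors (2 each). The lists hold no read counts, so what depth limits is not known. The cause was not tested for any of the changes below.

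The rank correlation of signal was 0.629 over shared peaks and 0.212 over all regions of the ranked list. Motifs higher at summits numbered 5, and 3 to 7 with either replicate left out. Motifs lower at summits numbered 2, but 4 by the median over 200 draws of the flank, with CAGGTG and CATATG added, 8 in peaks above the median signal, 6 with windows of 100 bp to each side, and 0 to 7 with either replicate left out. In peaks above the median signal, any E-box fell below its flanks (ratio 0.931, exact adjusted p = 0.0130, against 0.116 to 0.924 under the other alternatives). Gene lists passing the threshold numbered 1 higher and 1 lower. They numbered 1 to 2 higher and 1 to 2 lower with either replicate left out, 3 lower above the median signal, 2 higher and 3 lower both with q values of 0.05 or less and by nearest TSS, and 2 higher and 2 lower both within 1 kb of a TSS and with no length matching. Peaks near amos numbered 6 within 20 kb, 2 within 5 kb, and 2 to 5 with either replicate left out. The promoter share of peaks in replicate 1 alone differed from that of shared peaks by -9.02 points, and by 6.39 points when matched on signal decile.

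List differences from random lists, in percentage points, that changed sign were not called in either direction in the main list. By nearest TSS, they were 19.3 for neural precursor genes, 19.3 for Notch signalling, 11.5 for retinal determination, -19.5 for sensory cilium, -1.97 for gut, hemocyte and fat body, and 1.03 for segmentation. Within 1 kb of a TSS, they were 13.9 for neural precursor genes, 15.7 for Notch signalling, -15.3 for sensory cilium, -2.04 for glia, -5.36 for gut, hemocyte and fat body, and -26.8 for Hox. Notch signalling was also at 18.5 in the conservative list, 10.5 above the median signal, 4.13 with q values of 0.05 or less and 8.65 with no length matching, where retinal determination was at 5.31. In peaks above the median signal, the E(spl) and Brd list was at -20.5 and the gut, hemocyte and fat body list at -4.29. With either replicate left out, the ranges were -10.6 to 20.7 for Notch signalling, -6.35 to 39.5 for E(spl) and Brd, -18.4 to 0.151 for muscle and mesoderm, and -6.99 to 3.65 for gut, hemocyte and fat body.

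The Atonal-type E-box ratio was 1 with windows of 25 bp to each side and 0.986 with 100 bp, the CAAGTG ratio 1.02 with 25 bp and the CAATTG ratio 1.01 with 100 bp. The Scute-type E-box was called lower above the median signal (ratio 0.564, exact adjusted p = 0.0120) and in replicate 1 (0.739, adjusted p = 0.0119). With windows of 100 bp to each side it was also called lower (0.726, exact adjusted p = 0.000988). GAGAGAG had 0.713 in the conservative list, 0.452 above the median signal, 0.865 with q values of 0.05 or less and 0.658 to 1.5 with either replicate left out. The Su(H) site had 0.887 in the conservative list, 0.989 above the median signal and 0.882 to 0.995 with either replicate left out, CAACTG 0.977 in the conservative list, and the CA repeat 1.26 with flanks 2000 bp away and 0.471 to 1.21 with either replicate left out. Arm 2L had folds of 0.949 in the conservative list, 0.984 above the median signal, 0.984 with q values of 0.05 or less and 0.985 to 1.03 with either replicate left out. Arm X had 1.12, 1.09, 1.03 and 0.963 to 1.03 under the same alternatives, and 3R had 0.942 to 1.00 with either replicate left out.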

Other observations

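The tests on distal peaks (E-boxes and tRNA genes) and the repeated draws of the flank were chosen after the result was seen, and the tests of TSS strands and of tRNA gene sequence behind the distal E-boxes were not.

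Peaks away from promoters gathered at tRNA genes, which are transcribed by RNA polymerase III. Of 1075 summits over 1000 bp from a protein-coding TSS, 153 (14.2%, 95% interval 12.3 to 16.4) were within 100 bp of a tRNA gene, against a mean of 0.0656% and a maximum of 0.279% over 200 relocations. In the whole optimal list, 211 of 290 tRNA genes had such a summit. Both replicates had them, with 7.12% of all peaks of replicate 2 (205 of 2880) and 1.75% of those of replicate 1 (109 of 6213) at tRNA genes, against 0.0569% and 0.0587% after relocation. The replicates differed here: 17.0% of peaks in replicate 2 alone (102 of 599) were at tRNA genes. In replicate 1 alone 0.310% were (12 of 3873, Fisher's exact test, p = 4.01e-78). Highly transcribed tRNA genes may give signal in many pull-downs, and a control track was not used here to weigh that.

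At distal summits the share of any E-box was somewhat above that of flanks, but whether it was called depended on the flank drawn at random for the test. Any E-box was in 44.5% of the 1075 distal summit windows against 39.4% of flanks, a ratio of 1.13 (exact binomial test, p = 0.00616, BH adjusted over 21 motifs 0.0259), and passed the adjusted threshold in 68 of 200 draws of the flank. By the median over the draws it was not called (exact adjusted p = 0.0917). CACGTG had a ratio of 3.33 (exact adjusted p = 0.000487, 188 of 200 draws) and CAACTG one of 1.39 (adjusted p = 0.0436, 40 of 200 draws). Without the 153 summits at tRNA genes, and with the same flank for each of the other 922, the ratio of any E-box was 1.15 (exact p = 0.00361, adjusted 0.0189), so tRNA gene sequence does not account for the excess. The unadjusted p was then 0.05 or less in 176 of 200 draws and the adjusted p in 85, with a median adjusted p of 0.0657 (exact test), above the threshold. CACGTG had a ratio of 2.82 without them (exact adjusted p = 0.01, 100 of 200 draws, median adjusted p 0.0529). The CAACTG excess lay at tRNA genes, with a share of 17.0% there against 4.25% of flanks, and a ratio of 1.12 without them (exact adjusted p = 0.541, 0 of 200 draws). The Atonal-type E-box was in 0.651% against 0.605% (exact adjusted p = 1). The Scute-type E-box was in 1.77% against 1.86% (exact adjusted p = 0.881) and CAGCTG in 4.84% against 4.23% (adjusted p = 0.787). The excess of any E-box was thus not one of these types. CGATAG was also higher at distal summits, at 7.35% against 2.23% (exact adjusted p = 3.91e-06).

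Promoter peaks with CGATAG more often had TSSs of both strands nearby. Among promoter peaks, 39.7% (37.1 to 42.3) of the 1368 with CGATAG had TSSs of both strands within 500 bp of the summit, against 27.8% (26.3 to 29.5) of the 2984 without it (Fisher's exact test, two-sided, p = 1.24e-14). The summit lay between diverging TSSs, a minus-strand TSS to its left and a plus-strand TSS to its right, each within 500 bp, in 36.0% (33.5 to 38.6) and 22.9% (21.4 to 24.4) of them (Fisher's exact test, two-sided, p = 3.97e-19). Peaks with and without CGATAG were not matched on signal, which CGATAG went with, nor set against promoters without a peak. The differences therefore cannot be told apart from ones in peak strength or promoter type.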
